A study of Mus musculus with 24 samples.

How the data were processed

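RNA of mouse adrenal glands was hybridized to 24 one-colour Agilent arrays, 3 in each of 8 groups given by genotype (WT or Kcnk3 null), sex and treatment. Per the labels, RNA was extracted with a Qiagen kit and labelled with Cy3 by the Agilent low-input protocol. Each array holds 62976 features, of which 59305 are not controls and represent 55681 distinct probes.

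Per the file headers, the deposited raw files hold Feature Extraction spot intensities: mean and median foreground signal, median local background, and a processed signal from which the software had subtracted background. The deposited value table holds log2 values that the authors had quantile normalized between arrays over all features, controls included, without background subtraction; its scale and normalization were worked out from the values. The processed signal, from 2.49 to 535800.9, was used here on the log2 scale after subtracting each array's 75th percentile. Spots marked as outliers were left out, 160 to 283 per array, and spots of one probe were averaged. The signal limits precision: 57.0% to 64.7% of spots lay well above background, and the 75th percentile was 426 to 1099.

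Probe names were updated from a reference annotation by accession (26582 probes) or symbol (2602), or kept from the file (1638), and 24859 probes had no symbol. A probe was kept when its signal was well above background on at least 3 of the 24 arrays, which left 36832. The probe with the highest mean represented a symbol, and probes without one stood alone, giving 31026 features, 17849 with a symbol. Probe positions are those of mm9 in the files.

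Differences were tested in R 4.3.3 with limma 3.58.1, by linear models of the 8 group means with 16 residual degrees of freedom (lmFit and eBayes, prior degrees of freedom 2.23). Each p given for a gene is limma's moderated p with Benjamini-Hochberg adjustment over all features of a comparison, and a feature was called under 0.05. There were 15 comparisons: 10 of 2 groups, 3 averages over groups and 2 interactions. Other tools were the R package data.table (1.17.8), Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. In comparisons of 2 groups, where no array of one group was well above background, a fold change is given as a lower bound. In averages and interactions a gene with such a group is named without a size, apart from fitted values in the closing part. List medians use the fitted values of all members.

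Of 26 gene lists fixed before the data were examined, 25 were tested with camera at a preset correlation of 0.01, adjusted over all 375 pairs of list and comparison. This called 127 pairs. With an estimated correlation none of the 127 held, and fry, which tests whether the genes of a list move one way without comparing them with other genes, called 20. Members are also counted with p adjusted over the list alone.

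The rule for named genes was fixed beforehand too. It takes Kcnk3 in every comparison, the 12 largest rises and falls among called genes whose groups do not overlap, predicted and clone symbols skipped, and list members, called ones first and then those with the smallest p. Averages and interactions have no overlap condition. Some genes that the rule names are not reported here by name, and they stay in the counts and list tests. Chance separates 3 arrays from 3 in 10% of cases. All calls of the 10 comparisons of 2 groups were separated in this way, apart from 1 of 625 for sex in WT arrays. A call requires a large difference relative to the spread, so separation of called features is largely built in. It is no separate support.

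Arrays lay on 4 slides, the fourth holding 2 arrays. Replicate numbers were not treated as pairs: deviations from group means correlated by 0.227 on average between arrays of one number, with a minimum of -0.351. Alternatives were normexp background correction with quantile normalization, quantile normalization alone, the deposited value table, no filter and a filter on all arrays, all probes, replicate and slide blocks, RNA integrity as a covariate, array weights, a trended robust fit, omission of the fourth slide, and omission of each array. Omission of 2 arrays with liver transcripts and of 9 arrays with sex-linked signal against their label was added after the data were seen.

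The procedure was tested on simulated data, drawn as independent normal values around the mean of each feature with its residual spread. Changes were added to 200 of 30802 features in the arrays labelled female null sham. At a log2 change of 1 the procedure recovered 38 of 100 and at 2 it recovered 70 of 100. All were in the right direction, with 9 unchanged features called. In the male sham comparison of the same simulated data, where nothing was added, it called 0. The simulated data held no slide effect and no correlation between genes, so these figures need not carry over to the real arrays.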

Results

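RNA of mouse adrenal glands was measured on 24 one-colour arrays, 3 in each of 8 groups. The labels name WT mice and mice null for Kcnk3, the gene of the background potassium channel TASK1. Males were labelled sham or castrated, and females sham or testosterone injected. Between 57.0% and 64.7% of the spots on an array lay well above background, and no spot outside the controls was saturated. The number of arrays limits the precision. In the text, a difference is on the log2 scale with the standard error of the limma fit, for 3 arrays against 3 unless stated, and a feature was called at a Benjamini-Hochberg adjusted p under 0.05 among 31026 features, 17849 of them with a gene symbol.

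Kcnk3 was read first in each array, by a single probe at positions 30927090 to 30927149 of chromosome 5 (mm9), in the 3′ part of the gene. Whether this part is deleted in the null mice is not known from the sources used here, so residual signal does not test the labels. As a percentage of the mean of the WT sham arrays labelled with the same sex, Kcnk3 read 118, 111 and 71.0 in the male WT sham arrays 1, 2 and 3, and 116, 111 and 88.0 in the male WT castrated arrays. It read 37.9, 69.0 and 34.6 in the male null sham arrays and 22.0, 18.5 and 15.97 in the male null castrated arrays. Among arrays labelled female it read 86.0, 97.1 and 117 (WT sham), 68.2, 71.6 and 66.5 (WT testosterone), 29.9, 24.0 and 12.1 (null sham), and 5.63, 10.67 and 6.34 (null testosterone). Male null sham array 2, at 69.0%, lay next to male WT sham array 3, at 71.0%.

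The sex-linked transcripts went against several labels. Ddx3y and Eif2s3y, on the Y chromosome, read 25.4% and 45.5% of the male WT sham level in female WT sham arrays 2 and 3, and 32.9%, 19.2% and 36.0% in the female WT testosterone arrays, against at most 0.180% in the null arrays labelled female. Xist, made from the inactive X chromosome, read 19.5% and 18.3% of the female null sham level in male null sham arrays 1 and 2 and 17.4% and 58.0% in male null castrated arrays 1 and 2, against at most 1.11% in the WT arrays labelled male. In all, 9 arrays carried at least 10% of a signal of the opposite sex. Abhd1, a neighbour of Kcnk3, was high in every array labelled null, at 55.5% to 114% of the mean of the castrated null arrays, and also read 37.6%, 20.8% and 40.5% in the female WT testosterone arrays and 20.1% and 19.3% in male WT castrated arrays 2 and 3. Group names below are therefore those on the labels, and every direction is drawn between samples labelled in that way. Leaving the 9 arrays out, an alternative chosen after the data were seen, removes the female WT testosterone group and leaves 1 array each in female WT sham, male null sham and male null castrated. A lone array has no spread of its own and would be assumed to vary like the other groups, so beside the comparisons below the count is given only where every group compared keeps 3 arrays.

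**Figure D1:**
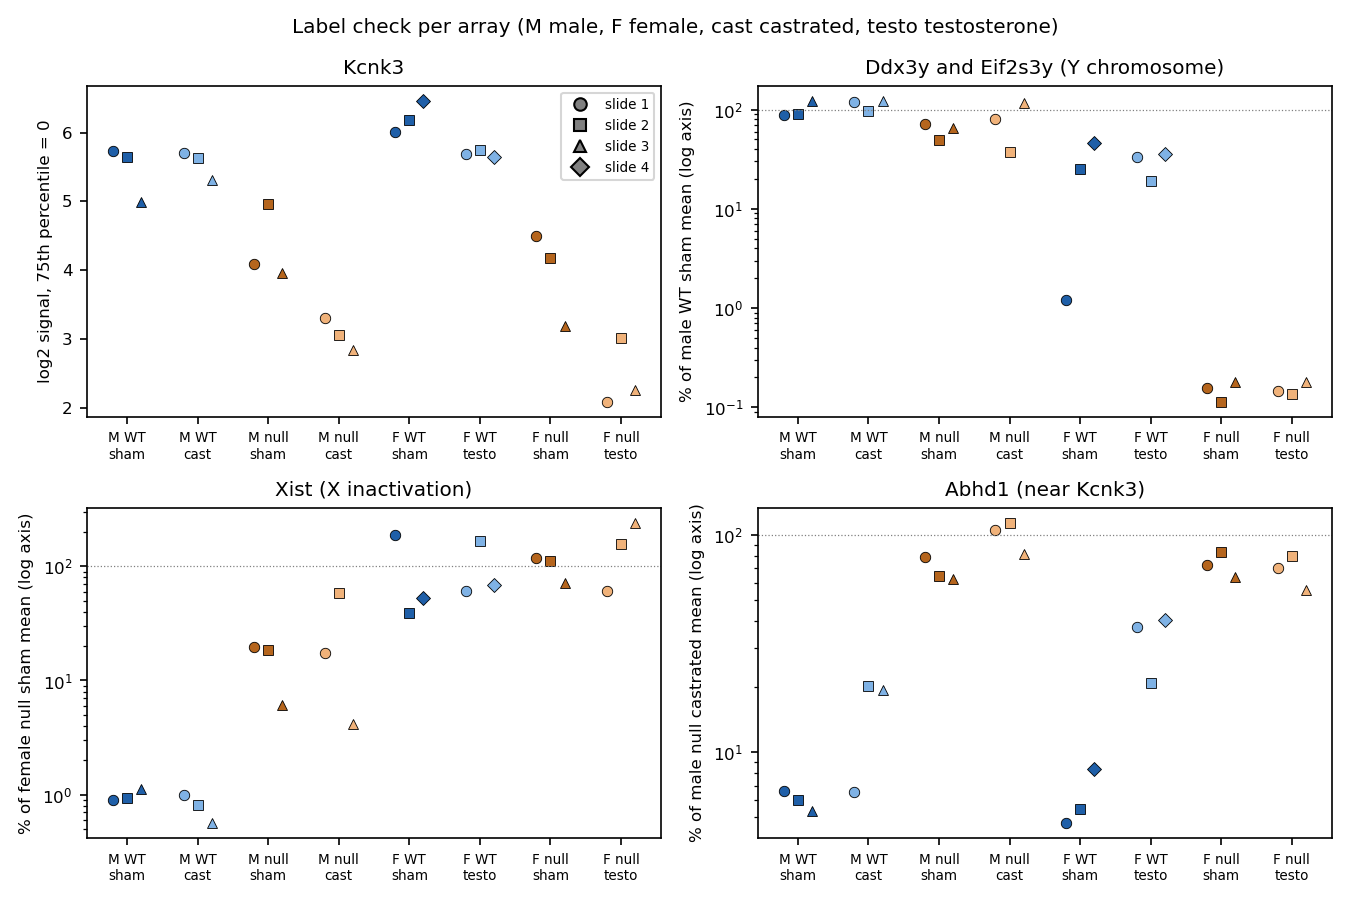
Kcnk3 signal on the log2 scale, and Y-linked, Xist and Abhd1 signal as a percentage of a reference group, in each of the 24 arrays. There is 1 point per array, and arrays are ordered by labelled group. The female WT testosterone arrays carry 19.2% to 36.0% of the male Y-linked signal, and the null arrays labelled female at most 0.180%.

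Null against WT in sham females asks what the loss of Kcnk3 does in the female gland. In arrays labelled female null sham, Tafa2, a chemokine-like secreted protein, was higher by 4.13 ± 0.44 (adjusted p = 0.000121), the neuropeptide Y receptor Npy1r by 3.07 ± 0.46 (adjusted p = 0.00237) and the secreted factor Ndnf by 2.94 ± 0.37 (adjusted p = 0.000597). Ankrd34b rose by 3.31 ± 0.31, Wipf3 by 2.78 ± 0.27 and Abhd1 by 3.61 ± 0.35 (each adjusted p = 4.27e-05). Caps2, Macc1 and Ano4 lay near background in all 3 female WT sham arrays and were at least 9.37-fold, 5.47-fold and 4.15-fold higher. Among falling genes were Kcnk3 itself (-2.27 ± 0.32, adjusted p = 0.0014), Tafa4 (at least 2.12-fold lower), the matricellular gene Ccn5 (-2.42 ± 0.46, adjusted p = 0.0175), the peptide precursor Ecrg4 (-1.96 ± 0.29, adjusted p = 0.00196) and the angiotensin II receptor Agtr1b (-1.70 ± 0.35, adjusted p = 0.0328). Eif2s3y and Ddx3y were at least 20.2-fold and 17.2-fold lower, because of the Y-linked signal in the WT arrays described above.

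Cholesterol synthesis and uptake was the list with the smallest camera p in this comparison. Of its 25 measured members 5 fell and none rose, among the fallers lanosterol synthase Lss (-1.61 ± 0.28, adjusted p = 0.00985), farnesyl diphosphate synthase Fdps (-1.59 ± 0.28, adjusted p = 0.0119), Insig1 (-1.63 ± 0.34, adjusted p = 0.0353) and Mvd (-1.41 ± 0.30, adjusted p = 0.0429), while adjusted over the list alone 18 fell. Insig1 lies within 5 Mb of Kcnk3 on chromosome 5, so its fall is not clear evidence for a shift of the list. The median was -1.06, with -1.28 on slide 1 and -1.04 on slide 2 (camera adjusted p = 5.41e-24; adjusted p = 0.0919 with an estimated correlation). Of 15 zona glomerulosa genes Agtr1b alone fell, and adjusted over the list alone 3 fell (median -0.17, adjusted p = 0.0131; adjusted p = 0.433 with an estimated correlation). No gene of the cell cycle list passed, with a median of 0.51 over 23 members (adjusted p = 1.32e-05; adjusted p = 0.618 with an estimated correlation). No adipocyte gene of 13 passed either, with a median of -0.64 (adjusted p = 4.55e-06; adjusted p = 0.433 with an estimated correlation). Outside called lists, the Wnt-related Dkk3 (1.81 ± 0.25, adjusted p = 0.00124) and the potassium channel genes Kcnq1 (1.44 ± 0.28, adjusted p = 0.0205) and Kcnmb4 (2.22 ± 0.47, adjusted p = 0.039) rose. Dkk3 may have been singled out by the study on these samples, so its place on the Wnt list is not independent evidence.

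In all, 146 features were called, 106 higher and 40 lower. The share higher was 72.6%, and 58.5% with normexp background correction and quantile normalization (241 features). The count was 217 with slide as a block. Leaving out female null sham array 1 or female WT sham array 3 gave 66 and 96 features.

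**Figure D2:**
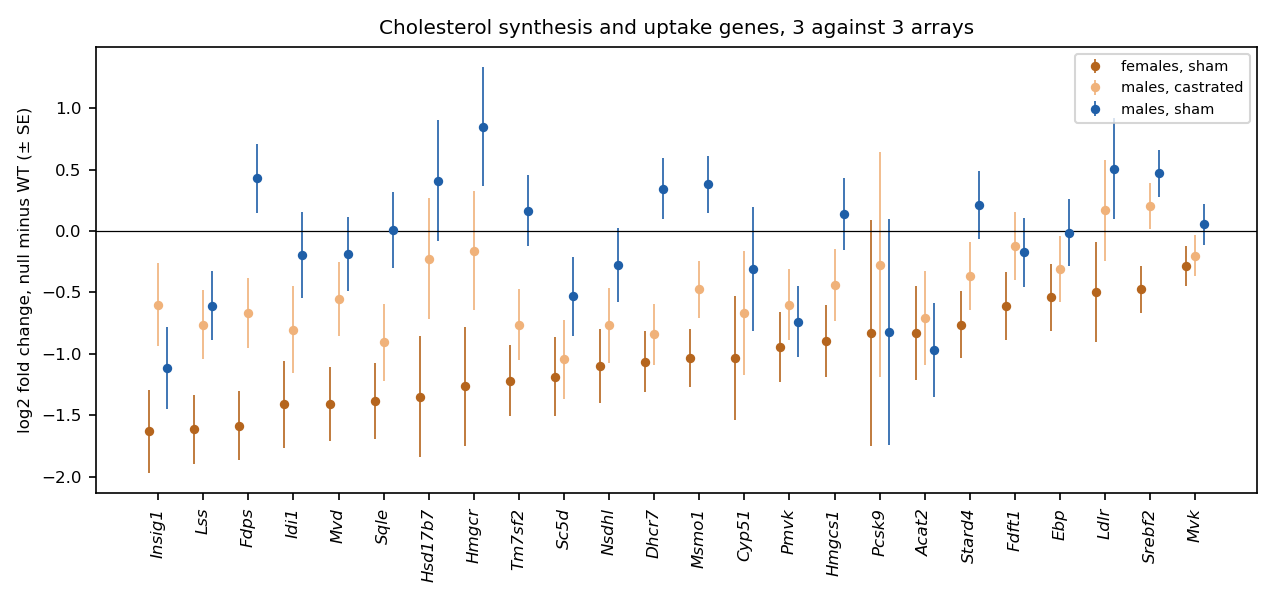
Reported measured members of the cholesterol synthesis and uptake list, called or not, as log2 differences with standard errors, in comparisons of null with WT arrays (n = 3 against 3). In sham females 5 of 25 measured members were called, all lower, and the median was -1.06.

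In castrated males the null and WT arrays were compared to ask what Kcnk3 does in the male gland without testicular androgen. Many of the genes named for sham females differed here too: Tafa2 rose by 4.20 ± 0.44 (adjusted p = 7.96e-05), Ankrd34b by 3.76 ± 0.31 (adjusted p = 2.97e-06), Wipf3 by 3.63 ± 0.27 (adjusted p = 1.66e-06) and Caps2 by 4.14 ± 0.56 (adjusted p = 0.000708), and Macc1 was at least 25.2-fold higher. The neurotrophin gene Bdnf (3.08 ± 0.54, adjusted p = 0.00699) and the acute-phase gene Saa3 (5.45 ± 0.75, adjusted p = 0.000753) also rose, and Xist, a sex marker, was at least 4.47-fold higher. Kcnk3 fell by 2.48 (adjusted p = 0.000478). Clic6 (-4.07 ± 0.43, adjusted p = 8.15e-05), Gulo, the gene of the last enzyme of vitamin C synthesis (-3.41 ± 0.56, adjusted p = 0.00409), Ecrg4 (-2.75 ± 0.29, adjusted p = 7.96e-05) and Pdzk1ip1 (-3.60 ± 0.60, adjusted p = 0.00469) fell, and Tgm5, Ccn5 and the Wnt inhibitor Wif1 were at least 11.1-fold, 5.38-fold and 2.54-fold lower.

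Zona glomerulosa genes went both ways in castrated males. Cyp11b2, aldosterone synthase, rose by 2.97 ± 0.49 (adjusted p = 0.00396), while Agtr1b (-2.59 ± 0.35, adjusted p = 0.000708) and the calcium sensor Vsnl1 (-3.24 ± 0.52, adjusted p = 0.00347) fell; the list had 1 riser and 2 fallers among 15 members, or 1 and 5 adjusted over the list alone (median -0.36, adjusted p = 0.00259; adjusted p = 0.371 with an estimated correlation). In the membrane potential and calcium list 3 of 25 members rose, among them the potassium channel Kcnq1 (1.88 ± 0.28, adjusted p = 0.0014) and the calcium pump Atp2b1 (0.87 ± 0.18, adjusted p = 0.0241), and 5 rose adjusted over the list alone (median 0.08, adjusted p = 0.00999; adjusted p = 0.424 with an estimated correlation). No cholesterol gene passed, with a median of -0.60 (adjusted p = 1.26e-08; adjusted p = 0.33 with an estimated correlation). No red blood cell gene passed, and adjusted over the list alone 3 of 10 rose (median 1.55, adjusted p = 4.11e-07; adjusted p = 0.406 with an estimated correlation). Dkk3 (2.01 ± 0.25, adjusted p = 0.000326) and Sfrp4 (1.49 ± 0.21, adjusted p = 0.000951), both secreted Wnt modulators, rose. The renin-angiotensin list, with Agtr1b alone falling among 12, had adjusted p = 0.0383, and adjusted p = 0.068 with slide as a block (adjusted p = 0.296 with an estimated correlation).

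There were 215 called features, 126 higher and 89 lower. A slide block gave 376. Leaving out male WT castrated array 1, 2 or 3 or male null castrated array 2 gave 112, 115, 133 and 128 features.

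Sham males labelled null and WT differed in fewer features. The innate immune genes Saa3 (4.98 ± 0.75, adjusted p = 0.00676) and Clec4e (at least 4.4-fold), the secreted Wnt antagonist Frzb (4.32 ± 0.56, adjusted p = 0.00166), the steroid reductase Akr1d1 (6.79 ± 1.20, adjusted p = 0.0412), Abhd1 (3.52 ± 0.35, adjusted p = 9.5e-05), Cst8 (2.78 ± 0.44, adjusted p = 0.0123), Ms4a10 (2.28 ± 0.41, adjusted p = 0.0428) and Mmel1 (1.39 ± 0.25, adjusted p = 0.0448) rose. Olr1, a scavenger receptor gene, was at least 3.05-fold higher, and Fam169a rose by 1.97 ± 0.35 (adjusted p = 0.0428). The difference in Kcnk3 did not pass (-1.12 ± 0.32, adjusted p = 0.656). No gene of the X-zone list passed, and adjusted over the list alone 2 of 3 rose (median 3.91, adjusted p = 3.44e-05; adjusted p = 0.157 with an estimated correlation), with medians of 6.38, 7.07 and -0.09 on slides 1, 2 and 3. Akr1c18 read 6.51 and 7.00 in male null sham arrays 1 and 2, which carried Xist at 19.5% and 18.3% of the female null sham level, and -3.65 in array 3, at 6.08%. On the same slides the difference was 9.09, 8.53 and 2.73 for Akr1d1 and 5.91, 6.75 and 2.28 for Saa3. These rises were larger on the slides of the 2 arrays with the higher Xist signal. Slide 3 also held male WT sham array 3, with albumin at 7.38 on the log2 scale. In castrated WT males, against the same sham arrays, Akr1d1 rose by 10.08, 8.81 and 5.74 on slides 1, 2 and 3. The pattern over slides can therefore not be credited to the Xist-carrying arrays alone. The Wnt list had Frzb alone rising among 30, and 2 adjusted over the list alone (median 0.19, adjusted p = 3.69e-06; adjusted p = 0.152 with an estimated correlation). The cell cycle list had none (median 0.58, adjusted p = 2.92e-09; adjusted p = 0.445 with an estimated correlation). Kidney and liver genes had a median of -1.32 with none passing (adjusted p = 0.0107; adjusted p = 0.553 with an estimated correlation); male WT sham array 3 carried albumin at 7.38 on the log2 scale, against at most 1.25 in the arrays other than this and female null testosterone array 1 (8.29).

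Of 25 called features, 24 were higher and 1 lower, with 34 calls with slide as a block. Leaving out any array but male null sham 3 gave 13 to 15 features, and leaving out the 2 arrays with albumin 16.

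Null and WT females given testosterone differed in a few falling genes. Kcnk3 (-3.25 ± 0.32, adjusted p = 0.000208), Tafa2 (-2.95 ± 0.44, adjusted p = 0.0162) and the secreted phospholipase Pla2g2e (-2.30 ± 0.37, adjusted p = 0.023) fell. Obp2a and Macc1 were at least 5.71-fold and 8.22-fold lower, and the Y-linked Ddx3y and Eif2s3y at least 52-fold and 56.9-fold lower, with Y-linked signal in all 3 WT arrays. Those arrays also had median shares of 14.4% to 38.7% over 13 features high in castrated null males (5.94% to 17.0% in the null testosterone arrays, with Y-linked signal of at most 0.180%), and against WT sham females Tafa2 was higher in them by 3.20 (SE 0.44, adjusted p = 0.0098) and Macc1 at least 8.09-fold. The lower Tafa2 and Macc1 here are thus relative to raised WT arrays. No gene of the X-zone list passed, and adjusted over the list alone 2 of 3 fell (median -6.10, adjusted p = 2.36e-05; adjusted p = 0.152 with an estimated correlation). Nor did any endothelial gene (median -0.20, adjusted p = 0.00318; adjusted p = 0.494 with an estimated correlation), though 2 of 14 fell adjusted over the list alone. Steroid synthesis had no passing member (median -0.12, adjusted p = 0.0362; adjusted p = 0.512 with an estimated correlation), and its p was 0.0759 with slide as a block; for the cell cycle list p went from 0.00627 to 0.824 with that block (adjusted p = 0.78 with an estimated correlation). There were 11 called features, 1 higher and 10 lower. The share higher was 9.09%, and 21.7% of 23 with normexp and quantile normalization. A slide block gave 28. Leaving out any array but female null testosterone 3 gave 4 to 7, and without the 9 arrays no WT testosterone array was left.

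Averaged over the 4 null and WT pairs, which draws on all 24 arrays, Kcnk3 fell by 2.28 (SE 0.16, adjusted p = 2.08e-07). Abhd1 (2.77 ± 0.17, adjusted p = 6.51e-08), Saa3 (2.63 ± 0.37, adjusted p = 0.000689), the clock gene Ciart (1.88 ± 0.34, adjusted p = 0.00574), Wipf3 (1.59 ± 0.13, adjusted p = 1.66e-06) and Ankrd34b (1.58 ± 0.15, adjusted p = 9.18e-06) rose. Pdzk1ip1 (-2.20 ± 0.30, adjusted p = 0.000551) and the cyclic GMP phosphodiesterase Pde5a (-1.87 ± 0.34, adjusted p = 0.00579) fell. Caps2 and Ndnf passed as higher and the proteoglycan Ncan and Ccn5 as lower, with no size given because at least 1 group was at background. Xist passed as higher and the Y-linked Ddx3y and Eif2s3y as lower, likewise without a size. Opposing sex-linked signal lay in WT arrays labelled female and in null arrays labelled male. It runs along the labelled genotype, and this contrast does not separate it from genotype. Of 25 cholesterol genes 9 fell, among them Lss (-1.002 ± 0.14, adjusted p = 0.000653), Insig1 (-1.17 ± 0.17, adjusted p = 0.000839) and Sc5d (-0.81 ± 0.16, adjusted p = 0.0105), and 15 adjusted over the list alone (median -0.43, adjusted p = 1.83e-13, and adjusted p = 0.186 with an estimated correlation). Insig1 lies within 5 Mb of Kcnk3 on chromosome 5, where DNA of another strain kept around the targeted gene stays open, as described below. In the membrane potential and calcium list 5 of 25 rose, among them Kcnq1, Atp1b1, Kcnmb4 and Atp2b1, with 6 up and 1 down adjusted over the list alone (median 0.05, adjusted p = 0.0472, and adjusted p = 0.223 with slide as a block; adjusted p = 0.494 with an estimated correlation). Mrap, the partner of the ACTH receptor, fell by 0.67 (SE 0.11, adjusted p = 0.00279), alone among 8 zona fasciculata genes (median -0.12, adjusted p = 0.0172; adjusted p = 0.433 with an estimated correlation). Of 39 genes fixed as neighbours of Kcnk3, 33 were measured; Abhd1, Cenpa and Slc35f6 rose and Atraid fell (median 0.07, adjusted p = 0.00523; adjusted p = 0.287 with an estimated correlation), and adjusted over the list alone 5 rose and 1 fell. This contrast called 741 features, 374 higher and 367 lower, 740 with one sign on slides 1 and 2. Calls were made from these same arrays, so one sign over slides is largely built in, here and in the contrasts below. With slide as a block 1044 were called, and leaving out male WT sham array 1 gave 488.

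**Figure D3:**
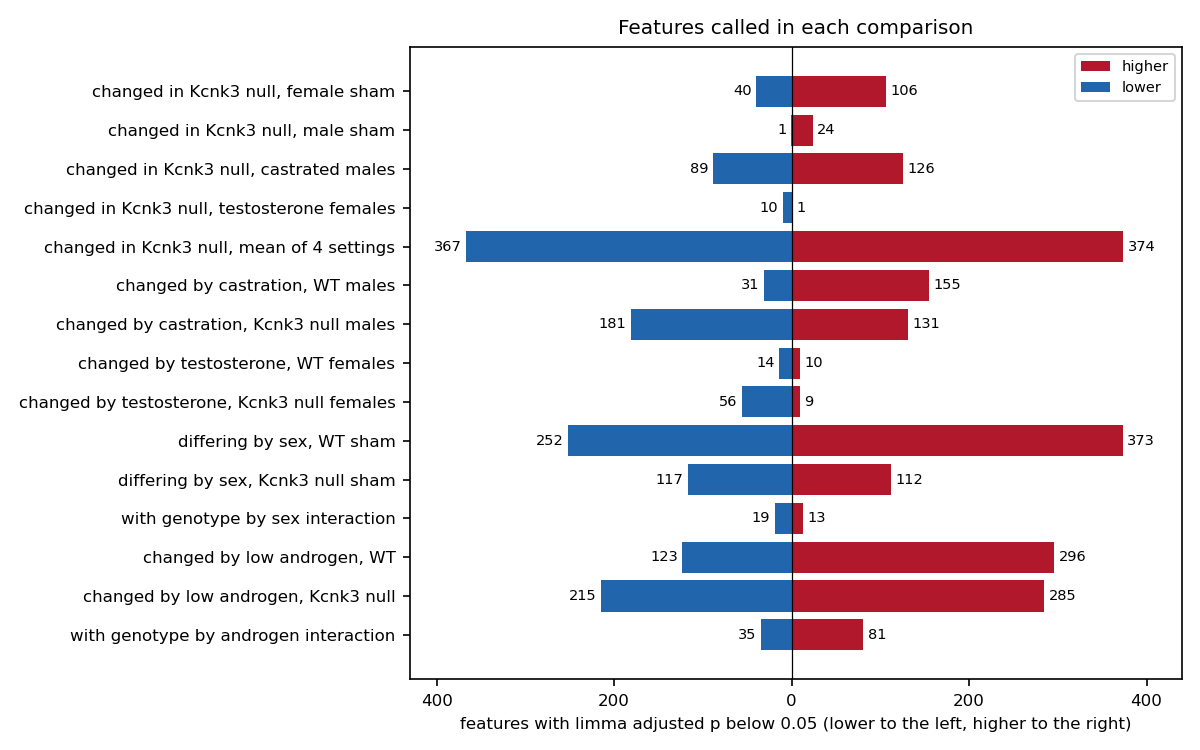
Features called in each of the 15 comparisons, higher and lower, at a Benjamini-Hochberg adjusted p under 0.05. Sex in WT sham arrays gave 625 calls, and testosterone in WT females 24.

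Castration of WT males shows the response of the gland to loss of testicular androgen. Of the genes of the X-zone, a transient inner cortical zone, Akr1c18, a progesterone-metabolising dehydrogenase, rose by 11.77 ± 1.75 (adjusted p = 0.00211), and Pik3c2g was at least 120-fold higher. With these, 2 of 3 X-zone genes rose, and all 3 adjusted over the list alone (median 8.47, adjusted p = 9.69e-11; adjusted p = 0.0793 with an estimated correlation), with medians of 8.43, 9.31 and 7.68 on slides 1, 2 and 3. The fatty acid hydroxylase Fa2h rose by 8.60 ± 1.07 (adjusted p = 0.000465), Akr1d1 by 8.21 ± 1.20 (adjusted p = 0.00186), the acid phosphatase Acpp by 5.75 ± 0.81 (adjusted p = 0.00153), Frzb by 5.44 ± 0.56 (adjusted p = 6.53e-05), Cst8 by 4.33 ± 0.44 (adjusted p = 6.3e-05) and Nrep by 4.22 ± 0.47 (adjusted p = 0.000176), and Clec4e was at least 5.3-fold higher. The potassium channel genes Kcnj4 (-2.45 ± 0.48, adjusted p = 0.0185), Kcnk1 (-1.81 ± 0.37, adjusted p = 0.0244) and Kcnf1 (at least 2.14-fold lower) fell, as did the thyroid hormone-binding Crym (-2.28 ± 0.40, adjusted p = 0.00799), the ligand Wnt9b (-2.21 ± 0.46, adjusted p = 0.0301), the ammonia channel Rhcg (-2.13 ± 0.46, adjusted p = 0.0389) and proenkephalin, Penk (-0.70 ± 0.12, adjusted p = 0.0066). Kcnk3 did not pass (0.09 ± 0.32, adjusted p = 1).

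Among the lists, 1 of 25 cholesterol genes rose, and 5 adjusted over the list alone (median 0.31, adjusted p = 0.000192; adjusted p = 0.5 with an estimated correlation). Akr1d1 and Akr1c18 rose among 19 steroid receptor and androgen metabolism genes, with 5 up and 1 down adjusted over the list alone (median 0.08, adjusted p = 0.0135; adjusted p = 0.33 with an estimated correlation). No red blood cell gene passed, and 8 of 10 fell adjusted over the list alone (median -2.10, with -3.77, -0.88 and -1.46 on slides 1, 2 and 3, adjusted p = 4.4e-11; adjusted p = 0.241 with an estimated correlation). The heme oxygenase Hmox1 fell by 1.28 (SE 0.26, adjusted p = 0.0254), alone among 25 glutathione and oxidative stress genes. Adjusted over the list alone, 1 rose and 3 fell, the median was -0.29 and the mean 0.02, and adjusted p = 0.0346 became 0.0975 with slide as a block (adjusted p = 0.553 with an estimated correlation). There were 186 calls, 155 higher and 31 lower. Blocking on slide gave 330. Leaving out any array but male WT sham 3 gave 81 to 113. Without the 9 arrays, all of other groups, 151 were called, 124 of them among the 186. Those arrays were chosen by sex-linked signal, which cannot show RNA of other males. Abhd1 read 20.1% and 19.3% of the castrated null mean in male WT castrated arrays 2 and 3. It read 6.53% in array 1 and 5.36% to 6.64% in the male WT sham arrays. The median share over 13 features high in castrated null males was 0.837% to 1.62% in the castrated WT arrays.

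Castration of null males asks for the same response without Kcnk3. The IgE receptor chain Fcer1a and the protease Mcpt2 were at least 11.6-fold and 3.66-fold higher, and chymase, Cma1, rose by 3.49 ± 0.52 (adjusted p = 0.00172). Macc1 and Obp2a were at least 31.4-fold and 29.4-fold higher, and the protease inhibitors Serpinb1c (4.22 ± 0.68, adjusted p = 0.00276) and Serpinb1a (3.64 ± 0.49, adjusted p = 0.000608), Tafa2 (4.08 ± 0.44, adjusted p = 7.41e-05) and Caps2 (3.15 ± 0.56, adjusted p = 0.00654) rose. Renin, Ren2 (2.44 ± 0.43, adjusted p = 0.0064), inhibin alpha, Inha (1.71 ± 0.30, adjusted p = 0.00601), the hedgehog target Gli1 (1.86 ± 0.36, adjusted p = 0.014) and Dkk3 (2.02 ± 0.25, adjusted p = 0.000319) rose as well. Susd3 (-6.10 ± 0.88, adjusted p = 0.00135), Clic6 (-4.94 ± 0.43, adjusted p = 1.57e-05), the co-activator Cited1 (-4.65 ± 0.65, adjusted p = 0.000932), Crym (-4.20 ± 0.40, adjusted p = 3.09e-05), Gulo (-3.55 ± 0.56, adjusted p = 0.00248), Kcnk1 (-2.97 ± 0.37, adjusted p = 0.000319) and Srd5a2, which makes dihydrotestosterone (-2.45 ± 0.56, adjusted p = 0.0402), fell, and Wif1 was at least 4.41-fold lower.

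In the zona glomerulosa list 1 of 15 genes rose, Cyp11b2 (2.16 ± 0.49, adjusted p = 0.035), and 3 fell, Agtr1b (-2.48 ± 0.35, adjusted p = 0.000938), Vsnl1 (-3.52 ± 0.52, adjusted p = 0.0016) and Shh (-1.44 ± 0.29, adjusted p = 0.0174). Adjusted over the list alone, 1 rose and 6 fell (median -0.32, adjusted p = 0.000517; adjusted p = 0.287 with an estimated correlation). The efflux pump Abcb1b (-1.65 ± 0.26, adjusted p = 0.00239) fell alone among 8 zona fasciculata genes, and 2 fell adjusted over the list alone (median -0.30, adjusted p = 0.00531; adjusted p = 0.413 with an estimated correlation). In the membrane potential and calcium list 2 of 25 genes rose, among them Kcnq1 (1.20 ± 0.28, adjusted p = 0.0413); adjusted over the list alone 5 rose and 1 fell (median 0.18, adjusted p = 0.0213; adjusted p = 0.433 with an estimated correlation). Of the 6 arrays 4 carried Xist at 10% or more, with 19.5% and 18.3% of the female null sham level in sham arrays 1 and 2 and 17.4% and 58.0% in castrated arrays 1 and 2. No X-zone gene passed, with 2 of 3 up adjusted over the list alone (median 3.95, with 1.28, 0.31 and 9.36 on slides 1, 2 and 3; adjusted p = 0.0337, and 0.0506 with slide as a block; adjusted p = 0.459 with an estimated correlation). Akr1c18 read 6.51 and 7.00 in sham arrays 1 and 2 and -3.65 in sham array 3. No gene of the unfolded protein response passed (median 0.20, adjusted p = 0.0488; adjusted p = 0.743 with an estimated correlation). Kcnk3 itself fell by 1.27 (SE 0.32) without passing (adjusted p = 0.0735), and passed with slide as a block (adjusted p = 0.0117), with -0.79, -1.90 and -1.12 on slides 1, 2 and 3. Of 312 calls 131 were higher and 181 lower. Fitting slide as a block gave 549. Leaving out any array but male null castrated 2 gave 137 to 190.

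Testosterone in WT females asks for the androgen response of the female gland. Tafa2 (3.20 ± 0.44, adjusted p = 0.0098), Abhd1 (2.40 ± 0.35, adjusted p = 0.0127), Ankrd34b (2.00 ± 0.31, adjusted p = 0.019), Wipf3 (1.74 ± 0.27, adjusted p = 0.019) and Penk (0.65 ± 0.12, adjusted p = 0.0499) rose, and Macc1 was at least 8.09-fold higher. The peptidase Mmel1 (-2.06 ± 0.25, adjusted p = 0.00266), the chloride channel Clcn2 (-1.12 ± 0.20, adjusted p = 0.0415), the kinase Mapk13 (-1.41 ± 0.26, adjusted p = 0.042) and the costimulatory ligand Icosl (-1.19 ± 0.20, adjusted p = 0.0342) fell, and Gadl1 was at least 2.12-fold lower. All 3 testosterone arrays carried the Y-linked and Abhd1 signals described above, and Kcnk3 did not pass (-0.53 ± 0.32, adjusted p = 1). Of 25 cholesterol genes 1 fell, and 3 adjusted over the list alone (median -0.43, adjusted p = 8.16e-09; adjusted p = 0.33 with an estimated correlation). No capsule and stroma gene passed, and adjusted over the list alone 1 of 16 rose, Col3a1 (median 0.35, adjusted p = 0.000272; adjusted p = 0.33 with an estimated correlation). The red blood cell list, with none passing (median 0.65, adjusted p = 0.0498; adjusted p = 0.763 with an estimated correlation), had adjusted p = 0.0792 with slide as a block.

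There were 24 calls, 10 higher and 14 lower. The share higher was 41.7%, and 19.0%, 27.9% and 18.8% under normexp, quantile normalization and the deposited value table, with 95, 43 and 85 calls. With slide as a block 151 were called, without the fourth slide 7, and each left-out array moved the count, to 4 or 5 without sham 2 or testosterone 3, 6 or 9 without testosterone 2 or sham 1, and 39 or 46 without testosterone 1 or sham 3; the 9 arrays include all 3 testosterone arrays.

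Testosterone in null females went against the castration response of null males. Tafa2 (-3.88 ± 0.44, adjusted p = 0.000669), Npy1r (-3.21 ± 0.46, adjusted p = 0.00458), Ankrd34b (-2.48 ± 0.31, adjusted p = 0.0014) and Cma1 (-2.68 ± 0.52, adjusted p = 0.0396) fell. So did Serpinb1a (-3.33 ± 0.49, adjusted p = 0.00493), Dkk3 (-1.52 ± 0.25, adjusted p = 0.0127) and Akr1d1 (-7.21 ± 1.20, adjusted p = 0.0134), and Macc1 was at least 5.57-fold lower. Nr0b1, a repressor of steroidogenic genes, fell by 2.56 (SE 0.28, adjusted p = 0.000669). Frzb (-3.04 ± 0.56, adjusted p = 0.0285) and Ndnf (-2.41 ± 0.37, adjusted p = 0.00727) fell too. Gulo (3.08 ± 0.56, adjusted p = 0.0281), Wif1 (2.54 ± 0.41, adjusted p = 0.0105), Rarres1 (2.33 ± 0.40, adjusted p = 0.0185), Clic6 (2.27 ± 0.43, adjusted p = 0.0348), the retinaldehyde dehydrogenase Aldh1a1 (1.90 ± 0.35, adjusted p = 0.0285) and Ecrg4 (1.504 ± 0.29, adjusted p = 0.0352) rose, with Tafa4 at least 1.68-fold higher. Female null testosterone array 1, on slide 1, carried albumin at 8.29 on the log2 scale. On slides 1, 2 and 3 the difference was 4.48, 2.06 and 2.71 for Gulo and -3.6, -9.7 and -8.3 for Akr1d1. A part of liver transcripts in these sizes is therefore not excluded. Castration in null males and testosterone in null females share no arrays. Between them 43 features were called in both, in opposite directions, and none in the same direction. Independent lists would share 0.236 rising with castration and 0.0525 falling. That reference is limited, since male null sham and castrated arrays 1 and 2 carried Xist and all comparisons share an estimate of spread.

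No X-zone gene passed, and all 3 fell adjusted over the list alone (median -4.91, adjusted p = 4.55e-06; adjusted p = 0.112 with an estimated correlation). Nor did any lymphocyte gene (median 1.11, adjusted p = 0.000252; adjusted p = 0.459 with an estimated correlation) or macrophage and antigen presentation gene (median -0.36, adjusted p = 0.012; adjusted p = 0.679 with an estimated correlation). For zona glomerulosa (median 0.08, adjusted p = 0.0498, 3 up adjusted over the list alone) the value with slide as a block was adjusted p = 0.0527 (adjusted p = 0.512 with an estimated correlation). Kcnk3 stayed short of the threshold (-1.504 ± 0.32, adjusted p = 0.0734) and passed with slide as a block (adjusted p = 0.00974), with -2.41, -1.17 and -0.94 on slides 1, 2 and 3. Of 65 calls 9 were higher and 56 lower. With slide as a block there were 148. Leaving out sham 1, sham 2 or testosterone 3 gave 19, 21 and 24. After removal of the 9 arrays, all of other groups, 40 were called, 23 of them among the 65.

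**Figure D4:**
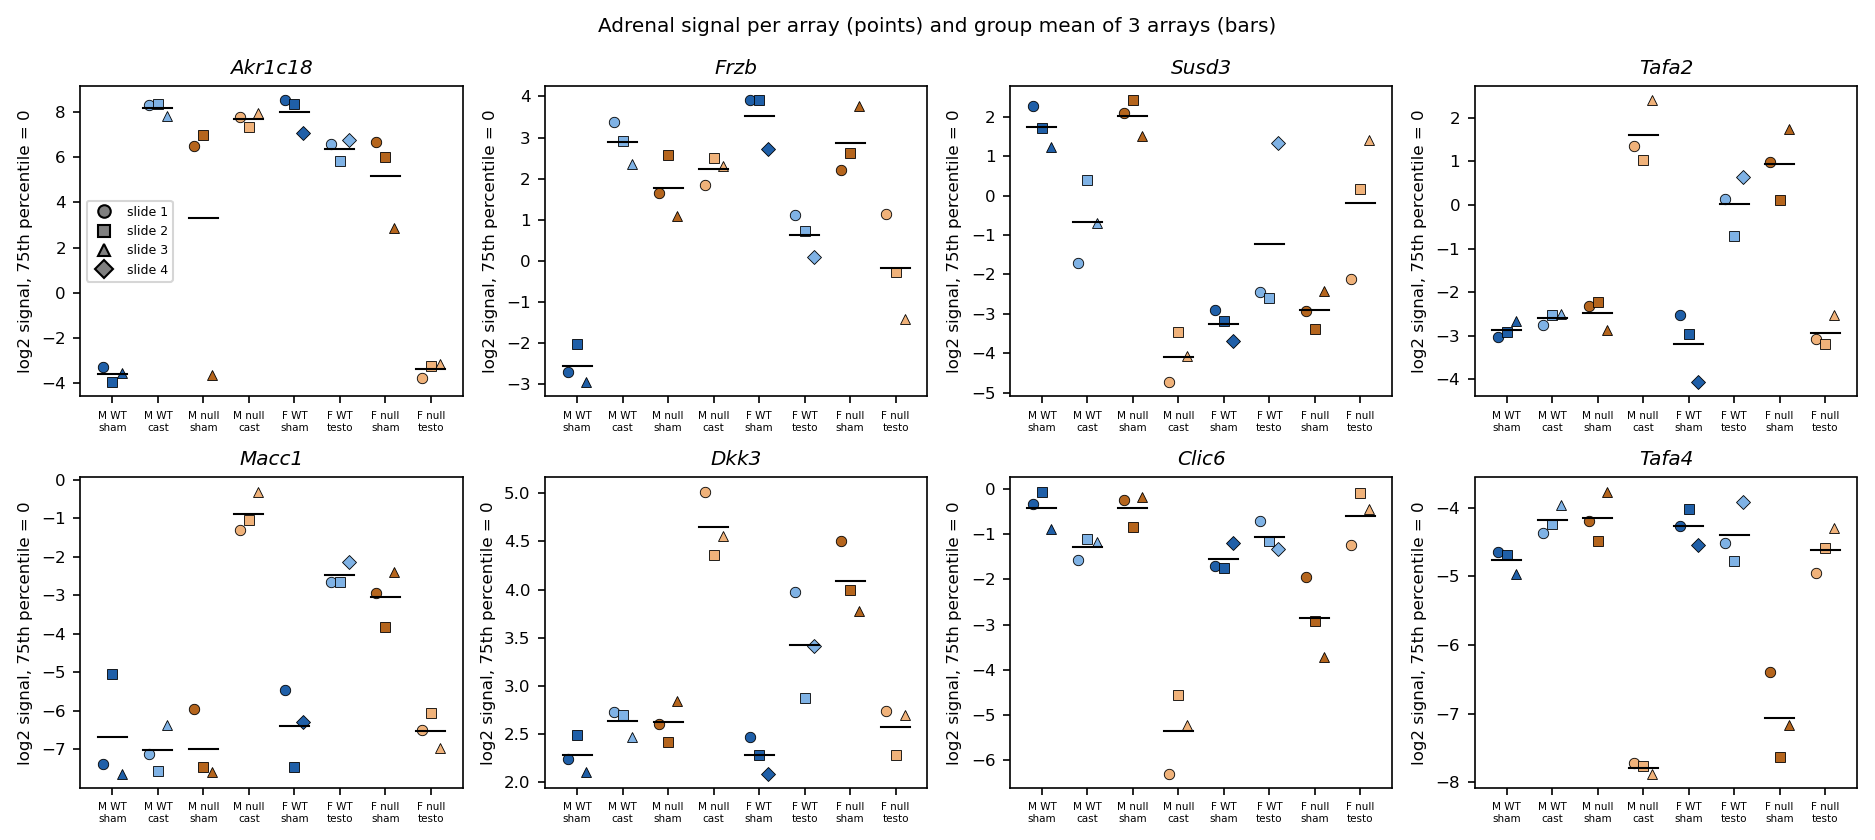
Normalized log2 signal of selected genes in each of the 24 arrays, 1 point per array, by labelled group. Tafa2, Dkk3 and other genes are higher in the null arrays labelled female sham or male castrated, and Tafa2 and Dkk3 also in the female WT testosterone arrays.

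Low androgen was also taken as the mean of castrated minus sham males and sham minus testosterone females (n = 12 arrays per genotype). In WT arrays Akr1c18 (6.68 ± 1.24, adjusted p = 0.00681), Akr1d1 (6.19 ± 0.85, adjusted p = 0.00058), Fa2h (5.54 ± 0.76, adjusted p = 0.000569), Frzb (4.15 ± 0.40, adjusted p = 3.14e-05) and Acpp (3.68 ± 0.58, adjusted p = 0.00165) rose, and the proteoglycan Acan (-2.29 ± 0.43, adjusted p = 0.00741), Kcnj4 (-2.08 ± 0.34, adjusted p = 0.00232), Srd5a2 (-1.94 ± 0.40, adjusted p = 0.0152), Crym (-1.92 ± 0.29, adjusted p = 0.00108) and Penk (-0.68 ± 0.09, adjusted p = 0.000307) fell. Pik3c2g passed as higher, with no size given because the male WT sham arrays were at background. All 3 X-zone genes rose, with or without being adjusted over the list alone (median 5.24, adjusted p = 1.15e-08; adjusted p = 0.0809 with an estimated correlation). Of 25 cholesterol genes 3 rose, among them Fdps (1.11 ± 0.20, adjusted p = 0.0054) and Msmo1 (0.76 ± 0.17, adjusted p = 0.0239), and 10 adjusted over the list alone (median 0.40, adjusted p = 1.12e-08; adjusted p = 0.33 with an estimated correlation). Nr5a1, the master regulator of steroidogenic cells, rose by 0.77 ± 0.18 (adjusted p = 0.0454). The macrophage and antigen presentation list, with no passing gene and 3 down adjusted over the list alone (median -0.09, adjusted p = 0.0498), had adjusted p = 0.0622 with slide as a block (adjusted p = 0.763 with an estimated correlation). There were 419 calls, 296 higher and 123 lower, 418 of one sign on slides 1 and 2. A slide block gave 829. Leaving out male WT sham 1, male WT castrated 1 or female WT sham 2 gave 273, 253 and 254. The female part of this contrast uses the 3 WT testosterone arrays with Y-linked signal.

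In null arrays the same low-androgen contrast raised Akr1c18 (6.49 ± 1.24, adjusted p = 0.00755), Tafa2 (3.98 ± 0.31, adjusted p = 2.06e-06), Serpinb1a (3.48 ± 0.34, adjusted p = 1.33e-05), Npy1r (3.16 ± 0.32, adjusted p = 1.84e-05), Cma1 (3.09 ± 0.37, adjusted p = 0.00011) and Ren2 (1.93 ± 0.31, adjusted p = 0.0015). Susd3 (-4.42 ± 0.62, adjusted p = 0.00054), Clic6 (-3.60 ± 0.31, adjusted p = 3.8e-06), corticosteroid-binding globulin, Serpina6 (-3.48 ± 0.64, adjusted p = 0.00543), the dopamine receptor Drd4 (-3.37 ± 0.72, adjusted p = 0.0175) and Gulo (-3.32 ± 0.40, adjusted p = 0.00011) fell. Serpina6 was -4.87, -2.47 and -3.10 on slides 1, 2 and 3, with the albumin-carrying female null testosterone array on slide 1. A part of liver transcripts in its size is therefore not excluded. Macc1 and Fcer1a passed as higher and Wif1 and Tafa4 as lower, each with a group at background and so without a size. Xist read 19.5% and 18.3% of the female null sham level in male null sham arrays 1 and 2. It read 17.4% and 58.0% in male null castrated arrays 1 and 2. Akr1c18 rose by 5.88, 4.78 and 8.80 on slides 1, 2 and 3. In the zona glomerulosa list Cyp11b2 rose (1.57 ± 0.34, adjusted p = 0.0211) and 4 genes fell, Agtr1b, Vsnl1, Shh and the potassium channel Kcnk9 (-1.16 ± 0.28, adjusted p = 0.0464). Adjusted over the list alone, 1 rose and 5 fell (median -0.08, adjusted p = 0.000517; adjusted p = 0.287 with an estimated correlation). Abcb1b (-1.24 ± 0.18, adjusted p = 0.000756) fell alone among zona fasciculata genes (median -0.10, adjusted p = 0.0296, and 0.0527 with slide as a block; adjusted p = 0.479 with an estimated correlation). There were 500 calls, 285 higher and 215 lower, 499 of one sign on each slide. Blocking on slide gave 764. Leaving out male null sham 1 gave 331.

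The interaction of genotype with androgen tests whether these responses differ between the genotypes, over all 24 arrays. It was positive for Tafa2 (5.44 ± 0.44, adjusted p = 3.01e-06), Npy1r (3.90 ± 0.46, adjusted p = 0.000213), Ankrd34b (3.89 ± 0.31, adjusted p = 3.01e-06), Bdnf (3.47 ± 0.54, adjusted p = 0.00426) and Dkk3 (2.16 ± 0.25, adjusted p = 0.000201), and negative for Gulo (-3.46 ± 0.56, adjusted p = 0.00584), Vsnl1 (-3.001 ± 0.52, adjusted p = 0.0102), Clic6 (-2.93 ± 0.43, adjusted p = 0.00292) and Agtr1b (-2.34 ± 0.35, adjusted p = 0.00295). Macc1 and Cma1 passed as positive and Tafa4 and Wif1 as negative, with no size given because groups were at background. The WT part of this contrast uses the 3 female WT testosterone arrays, which carried Y-linked signal and median shares of 14.4% to 38.7% over 13 features high in castrated null males, against 5.94% to 17.0% in the female null testosterone arrays. Tafa2, Ankrd34b and Macc1 were raised in those arrays against WT sham females, which adds to a positive interaction. In males alone, a test chosen after the data were seen that uses no testosterone array for the difference, castration moved null more than WT arrays in Tafa2 (by 3.81, SE 0.63, adjusted p = 0.021), Ankrd34b (by 3.30, SE 0.43, adjusted p = 0.00441), Clic6 (-4.08, SE 0.61, adjusted p = 0.0119) and Agtr1b (-2.85, SE 0.49, adjusted p = 0.0252), and Macc1, Tafa4 and Wif1 passed as well. It called 25 features, 22 of them among the 116, and Npy1r, Bdnf, Dkk3, Cma1, Gulo and Vsnl1 did not pass. In male null arrays 3, with Xist at 6.08% (sham) and 4.15% (castrated), Tafa2 read -2.87 and 2.41 and Clic6 -0.17 and -5.22. On slides 1 and 2 the interaction for Gulo was -4.6 and -2.8, with the albumin-carrying female null testosterone array on slide 1. Cyp11b2 did not pass (2.25 ± 0.49, adjusted p = 0.0507). Of 25 cholesterol genes 1 passed, with a negative value, and 6 were negative adjusted over the list alone (median -0.51, adjusted p = 8.31e-14; adjusted p = 0.181 with an estimated correlation). Kcnk3 did not pass (-0.19 ± 0.32, adjusted p = 1). There were 116 calls, 81 positive and 35 negative, all of one sign on slides 1 and 2. Fitting slide as a block gave 216; without the 9 arrays the contrast could not be made.

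WT sham females and males were compared for the sex difference of the gland. Females were higher in Akr1c18 (11.59 ± 1.75, adjusted p = 0.00118), Akr1d1 (8.66 ± 1.20, adjusted p = 0.000592), Fa2h (7.35 ± 1.07, adjusted p = 0.000867), Saa3 (6.72 ± 0.75, adjusted p = 6.6e-05), Frzb (6.06 ± 0.56, adjusted p = 1.09e-05) and Acpp (5.13 ± 0.81, adjusted p = 0.00175), and at least 109-fold higher in Pik3c2g, 20.1-fold in Xist, 16.4-fold in Clec4e, 11.4-fold in the itaconate-forming enzyme Acod1 and 5.9-fold in the chemokine Cxcl5. They were lower in Susd3 (-5.004 ± 0.88, adjusted p = 0.0041), Cited1 (-4.15 ± 0.65, adjusted p = 0.00157), Acan (-3.90 ± 0.60, adjusted p = 0.00146), Kcnj4 (-3.68 ± 0.48, adjusted p = 0.0003), Crym (-3.66 ± 0.40, adjusted p = 6.04e-05), the erythroid factor Gata1 (-3.30 ± 0.59, adjusted p = 0.00461) and Srd5a2 (-3.10 ± 0.56, adjusted p = 0.00502), and at least 2.46-fold lower in Kcnf1. For Kcnk3 no call was made (0.77 ± 0.32, adjusted p = 0.297). Ddx3y did not pass either (-3.33 ± 0.87, adjusted p = 0.0571), with Y-linked signal in female arrays 2 and 3.

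Of 20 measured steroid synthesis genes 3 were higher in WT females, Nr5a1 (1.62 ± 0.26, adjusted p = 0.00185), Por (0.85 ± 0.18, adjusted p = 0.0136) and the cholesterol transporter Star (0.84 ± 0.19, adjusted p = 0.0263), with 3 up and 1 down adjusted over the list alone (median 0.18, adjusted p = 0.00674; adjusted p = 0.433 with an estimated correlation). Ccnb1, a mitotic cyclin, rose (1.71 ± 0.42, adjusted p = 0.0413) alone among 23 cell cycle genes, and 15 adjusted over the list alone (median 1.00, with 1.41 on slide 1 and 0.87 on slide 2, adjusted p = 4.4e-11; adjusted p = 0.433 with an estimated correlation). Of 25 cholesterol genes 3 were higher, among them Fdps (1.20 ± 0.28, adjusted p = 0.0316) and Msmo1 (0.95 ± 0.23, adjusted p = 0.0413), and 6 adjusted over the list alone (median 0.39, adjusted p = 0.000383; adjusted p = 0.511 with an estimated correlation). Penk was lower (-0.94 ± 0.12, adjusted p = 0.000276), alone among 23 chromaffin cell genes (median -0.52, adjusted p = 0.0181, and 0.476 with slide as a block; adjusted p = 0.743 with an estimated correlation). There were 625 calls, 373 higher in females and 252 lower. With slide as a block there were 1385. Leaving out male 1, male 2 or female 1 gave 296, 302 and 333.

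Null sham females, against null sham males, were higher in Serpinb1c (3.84 ± 0.68, adjusted p = 0.00913), Tafa2 (3.43 ± 0.44, adjusted p = 0.000876), Npy1r (2.76 ± 0.46, adjusted p = 0.00587), Ankrd34b (2.71 ± 0.31, adjusted p = 0.000168), Dkk3 (1.47 ± 0.25, adjusted p = 0.00731) and Gli1 (1.71 ± 0.36, adjusted p = 0.0295), and at least 7.03-fold higher in Macc1 and 3.69-fold in Fcer1a. They were lower in Susd3 (-4.92 ± 0.88, adjusted p = 0.0103), Cited1 (-4.46 ± 0.65, adjusted p = 0.00206), Crym (-2.95 ± 0.40, adjusted p = 0.00126), Srd5a2 (-2.73 ± 0.56, adjusted p = 0.0245) and the angiotensin receptors Agtr2 (-1.60 ± 0.32, adjusted p = 0.0205) and Agtr1b (-1.57 ± 0.35, adjusted p = 0.0375), and at least 109-fold and 99.6-fold lower in Ddx3y and Eif2s3y. Both falling receptors are on the renin-angiotensin list of 12, where 4 fell adjusted over the list alone (median -0.28, adjusted p = 0.0136; adjusted p = 0.218 with an estimated correlation). No cholesterol gene passed and 8 were lower adjusted over the list alone (median -0.56, adjusted p = 2.26e-10; adjusted p = 0.287 with an estimated correlation). No cell cycle gene passed while 16 were higher adjusted over the list alone (median 0.97, adjusted p = 4.06e-12; adjusted p = 0.416 with an estimated correlation). For Kcnk3 the test did not pass (-0.38 ± 0.32, adjusted p = 0.813). Male null sham arrays 1, 2 and 3 carried Xist at 19.5%, 18.3% and 6.08% of the female null sham level. The differences in this comparison are thus between arrays as labelled. Signal of the opposite sex in the male arrays may have changed their size. There were 229 calls, 112 higher and 117 lower. A slide block gave 579. Of the 229 calls 48.9% were higher, and 38.4% and 38.6% with quantile normalization and the deposited value table. Leaving out any array but female 2 gave 65 to 132.

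The genotype by sex interaction, over the 12 sham arrays, was positive for Tafa2 (3.74 ± 0.63, adjusted p = 0.0259), Ankrd34b (2.85 ± 0.43, adjusted p = 0.0141), Wipf3 (2.65 ± 0.38, adjusted p = 0.0104) and the Eph receptor Epha8 (2.18 ± 0.39, adjusted p = 0.0325), and negative for Frzb (-4.97 ± 0.79, adjusted p = 0.0189), Cst8 (-4.14 ± 0.62, adjusted p = 0.0141) and Mmel1 (-2.59 ± 0.36, adjusted p = 0.00904). Clec4e and Tafa4 passed as negative, each with a group at background and so without a size. Female WT sham arrays 2 and 3 and male null sham arrays 1 and 2, with signal of the opposite sex, enter this contrast. Kcnk3 did not pass (-1.15 ± 0.45, adjusted p = 0.742). Of 25 cholesterol genes 1 passed, with a negative value, and 14 were negative adjusted over the list alone (median -1.01, adjusted p = 8.44e-19; adjusted p = 0.11 with an estimated correlation). There were 32 calls, 13 positive and 19 negative, all of one sign on slides 1 and 2. Blocking on slide gave 71. The share positive was 40.6%, and 22.0% and 21.7% with normexp and the deposited value table. Leaving out any array but female null sham 3 moved the count, to between 3 and 62.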

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

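The tests of explanations for the 3 patterns weighed in this part were chosen only after the results were seen, as was the test of the interaction in males alone, and the other interaction tests were planned.

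The effect of the null genotype differed between sham females and sham males in 32 features by the interaction test. Among those chosen by the rule for named genes the difference was positive for Tafa2 (3.74), Ankrd34b (2.85), Wipf3 (2.65), DXBay18 (2.32) and Epha8 (2.18). It was negative for Frzb (-4.97), Clec4e (-4.32), Cst8 (-4.14), Nrep (-3.86), Ms4a10 (-3.42) and Tafa4 (-3.41). A group was at background for Clec4e and Tafa4, so their values are fitted and not measured sizes. Lists that differed had medians of -3.30 (sex chromosome control), -0.26 (steroid synthesis), -0.36 (zona glomerulosa), -0.37 (zona fasciculata), -7.10 (X-zone), 1.54 (red blood cells) and -1.01 (cholesterol synthesis and uptake). None of these list calls held with an estimated correlation.

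The effect of low androgen differed between null and WT arrays in 116 features. The difference was positive for Macc1 (6.90), Tafa2 (5.44), Npy1r (3.90), Ankrd34b (3.89), Caps2 (3.60) and Bdnf (3.47). It was negative for Gulo (-3.46), Tafa4 (-3.40), Wif1 (-3.38), Tgm5 (-3.10), Vsnl1 (-3.001) and Clic6 (-2.93). Groups were at background for Macc1, Caps2, Tafa4, Wif1 and Tgm5, so their values are fitted and not measured sizes. For Gulo the difference was -4.6 on slide 1, which holds the albumin-carrying female null testosterone array, and -2.8 on slide 2. The WT part uses the 3 female WT testosterone arrays, in which Tafa2, Ankrd34b and Macc1 were raised and the median share over 13 features high in castrated null males was 14.4% to 38.7%, against 5.94% to 17.0% in the female null testosterone arrays. In males alone, where no testosterone array enters the difference, 25 features were called, 22 of them among the 116. There the difference was 3.81 for Tafa2 (SE 0.63), 3.30 for Ankrd34b (SE 0.43), -4.08 for Clic6 (SE 0.61) and -2.85 for Agtr1b (SE 0.49), and Macc1, Tafa4 and Wif1 also passed, so the signal in the testosterone arrays alone does not account for these 7. All 116 kept their sign, which is partly built in because the male arrays enter both tests; for calls that did not pass in males the part of that signal stays open. Lists that differed had medians of -0.38 (zona glomerulosa), -0.19 (zona fasciculata), 0.23 (capsule and stroma), 0.26 (macrophages and antigen presentation), -0.62 (lymphocytes), 0.24 (endothelium), 1.68 (red blood cells) and -0.51 (cholesterol synthesis and uptake). None of these list calls held with an estimated correlation.

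The female WT testosterone arrays carried Y-linked transcripts together with genes high in castrated null males. A response of WT females to testosterone is argued against for the Y-linked part, since the lowest Y-linked share of the 3 arrays was 19.2% of the male level. A swap of whole samples is argued against, since the highest median share over 13 features high in castrated null males was 38.7%. Whether RNA of castrated null males was mixed into these samples stays open. With castrated null males as the reference for both, the median share over the Y-linked share was 0.920, 0.585 and 0.671 in arrays 1, 2 and 3. In array 2 this lies beyond a factor of 1.5 from 1, with quartiles over the features of 0.360 and 0.860 that reach inside it. Female null testosterone array 3 had a median share of 17.0% with a Y-linked signal of 0.180%, so a share of the size in WT array 2 also occurs without Y-linked signal.

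The first principal component, with 22.1% of the variance, set slides 3 and 4 apart from slides 1 and 2. Among arrays of RNA integrity number 7 or 8 the highest score on slide 3 was -16.1 and the lowest on slides 1 and 2 was -10.3, which argues against low RNA integrity for slide 3 and may point to a slide batch. On slide 4 both arrays had a number of 3 and 0 other arrays did, so batch and RNA integrity cannot be told apart there. No biological explanation was tested.

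Features within 5 Mb of Kcnk3 on chromosome 5 were called more often in the averaged null and WT contrast than those elsewhere, at 9.72% against 2.35%. The two-sided Fisher p of this excess, 6.72e-08, and the higher one-sided p of its 2 sides, 0.0014, measure the pattern itself. They do not decide between a response to the loss of Kcnk3 and DNA of another strain kept around the targeted gene, and both stay open. Several probes can hit one transcript, so features are not independent.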

How the results depend on the processing

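Omission of arrays with liver transcripts and of arrays with opposing sex-linked signal, and the genotype by androgen test in males only, were chosen after the data were seen, and the other alternatives were planned. Of 449 gene results 438 were called. Of these, 160 kept their direction and call under all alternatives that gave them a value. Under all planned ones other than leaving out single arrays 309 did so, and 0 reversed. An alternative without a value for a result did not count against it. The filter on all arrays gave 294 the same and 1 stronger, and no value for the rest. Omissions that empty a group give none for its comparisons either. Signal over background limits what can be tested, since 57.0% to 64.7% of spots lay well above background. Fewer probes or arrays by construction act in the filters and omissions; otherwise the cause was not tested.

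The number of called pairs of list and comparison, 127, was 0 with an estimated correlation and 20 with fry. With normexp and quantile normalization the counts were 241 (null, sham females), 13 (null, sham males), 23 (null, testosterone females) and 95 (testosterone, WT). With quantile normalization alone testosterone in WT females gave 43, and with the authors' processed values 85, with 231 for null sham females. Without a filter there were 434 (averaged genotype), 7 (testosterone, WT), 33 (testosterone, null), 19 (genotype by sex) and 77 (genotype by androgen). With probes above background on all arrays there were 15 (null, sham males), 4 (null, testosterone females) and 42 (testosterone, WT). Testing all probes gave 19 for null testosterone females, and a trended robust fit 40 for testosterone in WT.

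With the replicate block counts were 278 (null, sham females), 325 (null, castrated males), 48 (null, testosterone females), 1372 (averaged genotype), 82 (testosterone, WT), 119 (testosterone, null), 1017 (sex, WT), 405 (sex, null), 67 (genotype by sex) and 186 (genotype by androgen). The numbers are not treated as pairs, so these stand as an alternative.

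With slide as a fixed block counts were 376 (null, castrated males), 28 (null, testosterone females), 330 (castration, WT), 549 (castration, null), 151 (testosterone, WT), 148 (testosterone, null), 1385 (sex, WT), 579 (sex, null), 71 (genotype by sex), 829 (low androgen, WT), 764 (low androgen, null) and 216 (genotype by androgen). As a random block, with a correlation of 0.316, slide gave, in the order null sham females, null sham males, null castrated males, null testosterone females, averaged genotype, castration WT, castration null, testosterone WT, testosterone null, sex WT, sex null, genotype by sex, low androgen WT, low androgen null and genotype by androgen, 282, 44, 425, 44, 1224, 321, 594, 145, 161, 1177, 624, 91, 836, 826 and 249. Array weights, from 0.208 to 3.33, gave in the same order 1288, 711, 957, 349, 2871, 1268, 1646, 503, 474, 3098, 2309, 1033, 1672, 1549 and 835. RNA integrity as a covariate gave 18 (null, testosterone females), 1336 (averaged genotype), 65 (testosterone, WT), 1066 (sex, WT), 369 (sex, null) and 62 (genotype by sex).

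Without the fourth slide counts were 5 (null, testosterone females), 7 (testosterone, WT) and 75 (genotype by sex). Without the arrays with liver transcripts they were 222 (null, sham females), 16 (null, sham males) and 7 (null, testosterone females). Without the 9 arrays of opposing sex-linked signal they were 62 (null, sham females), 5 (null, sham males), 23 (null, castrated males), 12 (castration, null), 40 (testosterone, null), 21 (sex, null), 3 (genotype by sex) and 103 (low androgen, null). That omission leaves no female WT testosterone array, so 5 comparisons have no value, and 1 array each in female WT sham, male null sham and male null castrated. Of the comparisons listed only testosterone in null females keeps 3 arrays in each group. A lone array is assumed to vary like the other groups, so a lower count does not show that calls rest on the omitted arrays. In males only, genotype by androgen gave 25. Lists were not run with the authors' processed values, all probes, the random block, array weights or the trended fit.

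Leaving out each array gave 66 to 129 (null, sham females), 13 to 25 (null, sham males), 112 to 176 (null, castrated males), 4 to 10 (null, testosterone females), 488 to 945 (averaged genotype), 81 to 131 (castration, WT), 137 to 214 (castration, null), 4 to 46 (testosterone, WT), 19 to 68 (testosterone, null), 296 to 672 (sex, WT), 65 to 165 (sex, null), 3 to 62 (genotype by sex), 253 to 521 (low androgen, WT), 331 to 535 (low androgen, null) and 80 to 146 (genotype by androgen).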

Other observations

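The overlaps and window values in this part were chosen after the results were seen, and the splits of the arrays were planned.

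Of the 146 features called between null and WT sham females, 72 were also called between null and WT castrated males, which share no arrays with them: 59 higher and 13 lower in both and none in opposite directions, against 0.431 and 0.115 for independent lists. Castration and testosterone went opposite ways in 13 features in WT arrays, 11 rising and 2 falling with castration. Sex gave 82 features called in both genotypes in one direction, 26 higher and 56 lower in females. Castration gave 30 called in both genotypes, 13 higher and 17 lower. Groups without shared arrays may still not be independent. Male null castrated arrays 1 and 2 carried Xist at 17.4% and 58.0% of the female null sham level. Female WT sham arrays 2 and 3 carried Y-linked signal at 25.4% and 45.5% of the male WT sham level. In the 3 female WT testosterone arrays, used in the overlap of castration and testosterone in WT arrays, it was 19.2% to 36.0%. All comparisons also share an estimate of spread, so the values for independent lists are a limited reference.

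Lists for gonadal-like cells, two-pore potassium channels and immediate early genes were called in no comparison, with smallest camera adjusted p of 0.267, 0.179 and 0.0743. Single members still passed: Inha rose with castration in null males (1.71) and Kcnk1 fell (-2.97).

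With slide as a block, lists not called otherwise were called for the unfolded protein response in null against WT sham females (camera adjusted p = 0.0249), null against WT testosterone females (0.00145), testosterone in null females (0.0430), sex in WT arrays (0.00313) and genotype by sex (0.0139). The same holds for chromaffin cells (0.00632) and renin-angiotensin (0.0321) in testosterone females. For genotype by sex it holds for chromaffin cells (0.0488), renin-angiotensin (0.0244), kidney and liver tissue (0.0231), cell cycle (0.00994) and steroid receptors (0.0419), and for sex in WT arrays for macrophages (0.0417). These use the preset correlation; with an estimated correlation and no block 0 of 375 pairs were called, and an estimated correlation was not run with the block.

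Features 5 to 15 Mb from Kcnk3 were called at 15.9% (35 of 220, Fisher p = 7.23e-19) in the averaged genotype contrast, those 15 to 30 Mb away at 4.79% (7 of 146, p = 0.0911) and the rest of chromosome 5 at 2.08%. Features with a symbol within 15 Mb were called at 7.52% (17 of 226). Albumin read 8.29 in female null testosterone array 1 and 7.38 in male WT sham array 3, on the log2 scale, and at most 1.25 in the others.

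Other splits of the same arrays were counted for each comparison. For the 10 comparisons of 3 against 3 the 10 splits are too few for a share under 0.05. The real count and the highest of the other splits were 146 and 1 (null, sham females), 25 and 0 (null, sham males), 215 and 1 (null, castrated males), 11 and 4 (null, testosterone females), 186 and 1 (castration, WT), 312 and 1 (castration, null), 24 and 378 (testosterone, WT), 65 and 0 (testosterone, null), 625 and 0 (sex, WT), and 229 and 0 (sex, null). For testosterone in WT females 2 of 10 splits, the real one included, gave as many; the other, with 378, points to a structure of the samples that was not identified. It puts both arrays of the fourth slide on one side, but the remaining 8 splits gave at most 2, including 3 that do the same, so the slide alone does not account for it. The real count was 151 with slide as a block.

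Among 100 splits, chance can be excluded at 0.05 for the averaged genotype contrast (2 as large, 741 against 3578), low androgen in WT (1, 419 against 267) and low androgen in null (1, 500 against 123). The same counts were made for genotype by sex (2, 32 against 89) and genotype by androgen (2, 116 against 439). Their splits shuffled genotype within each sex and treatment, which removes the genotype effect as well. They do not test an interaction alone, so chance is not excluded for these interactions. The split with 3578 follows the slides, a structure of the samples, and the real count was 1044 with slide as a block. The split with 89 exchanges the genotypes of all 6 sham females, which turns the interaction into the sum of the genotype effects of both sexes, with its sign changed. That with 439 exchanges the genotypes of all 6 testosterone females and of 2 sham males of each genotype, so the genotype effect no longer cancels. The structure of the samples behind both is the labelled genotype, and no other was tested.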
